A study of Arabidopsis thaliana with 64 samples.

How the data were processed

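RNA-seq was analysed from leaves of Arabidopsis thaliana grown for 4 weeks with 16 hours of light a day. Per the labels, total RNA was sequenced from single ends of 50 bases on an Illumina HiSeq instrument. The labels describe 64 libraries, of which 40 have a column of values and 24, from 4 genotypes labelled wrky, were not analysed here. The 40 libraries form 15 groups of 5 genotypes and 3 treatments, taken from the labels, with 3 libraries per control or dehydration group and 2 per starvation group. DSK2 RNAi is a knockdown line, bes1-D a gain-of-function line, bri1-301 a weak receptor allele and atg7-2 an autophagy mutant.

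The authors deposited a signal per gene and library under the name RPM, per the file headers. The values are called a signal here because the authors' columns sum to 985308 to 1023136 rather than to one fixed total, and what reads the authors divided by is not given in the sources used here. GSNAP, DESeq2 and TAIR10 are named per the submitters' processing notes, with no versions, roles or settings given. How reads of similar or overlapping genes were counted, and whether strand was used, is not given in the sources used here. The authors' deposited table also holds a yes or no per gene for 14 comparisons, whose test and threshold are not given in the sources used here. Of 33366 lines 4591 had no gene identifier and were left out, leaving 28775 genes. Symbols came from a gene table of the TAIR10.1 assembly, in which 28009 identifiers matched and 10610 genes had a symbol. That assembly may differ from the one the authors used, so no coordinates are given and it served for names, gene order and transcript lengths only. All 279 organelle genes are listed at 0.

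With a tolerance of 0.01 reads, 100.0% of values in each library were whole multiples of 1 read, at 26.3 to 29.8 reads per RPM. Depth was therefore similar across libraries. A floor of 3 reads in a library is 0.101 to 0.114 RPM and covers counting error only. Replicates differed by more than sampling noise, since the lowest chi-square per degree of freedom between replicates was 14.8.

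Values were tested as log2(RPM + 0.5), on which the changes of low genes are understated. Genes with at least 1 RPM in at least 2 libraries were kept, 19824 in all. limma with a mean-variance trend was fitted to all 40 libraries by group (25 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method within each of 22 comparisons, with calls at adjusted p under 0.05. The comparisons were dehydration and starvation against control in each genotype, each mutant against WT in control, and the interaction of each mutant with each treatment. The tests are two-sided. With 2 starvation libraries per group the spread rests on all groups together. The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. They had assumed RPM summing to a fixed total and 64 libraries. The other unit does not change the test. With 4 genotypes not analysed here, dehydration-responsive genes had to pass in 2 of the 3 other mutants, in place of 5 of 7.

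The 21 gene lists hold 356 members, all present in the table: ABA and dehydration, brassinosteroid biosynthesis, brassinosteroid- and auxin-induced growth, autophagy, sugar starvation, branched-chain amino acids, senescence, photosynthesis, salicylic acid and defence, jasmonate, glucosinolate, flavonoid, cell cycle, heat shock, 26S proteasome, circadian clock, and markers of guard cells, phloem, xylem, epidermis and floral organs. Each was tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusting over the lists of a comparison. Of 462 list tests 190 were called with the preset and 19 with the estimated correlation. Counts adjusted over the list alone stand beside those over all genes.

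Genes were named by rule. Targeted genes were named wherever a genotype was first compared. In WT under each stress the rule took up to 3 called members of each list by size of change, with the 5 most raised and 5 most lowered genes. For a mutant against WT it took the 4 most raised and 4 most lowered genes and up to 2 members of each called list, and for an interaction the 2 most raised and 2 most lowered. Genes taken from all genes had to pass, to have 5 RPM in the higher group, a symbol and, except in interactions, no overlap between libraries. Stress responses of the mutants name only genes named for WT. Other genes are said to be chosen after their values were seen.

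The fit was tested on simulated data of 19824 genes, 100 changed at each fold. For dehydration in WT it recovered 26% of 2-fold and 86% of 4-fold changes with 4 false calls, for starvation in WT 15% and 83% with 2, and for bes1-D in control 30% and 85% with 7. For bes1-D interactions it recovered 8% and 58% with 3 under dehydration and 8% and 45% with 3 under starvation. Regrouped atg7-2 libraries gave up to 99 calls, so real false calls may be more.

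Alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 5 RPM, a further median-of-ratios scaling, only the compared libraries, a replicate block shared by all groups, a replicate block within each genotype with the starvation libraries left out, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, an estimated correlation, and each library left out. Chosen after seeing the data were removing each library's trend with transcript length, its length slope as a covariate, leaving out 6 libraries that stand apart by that slope, a replicate block of the WT and DSK2 RNAi controls, and removing the length trend in the fits with a block. Lengths were known for 19697 tested genes (99.4%). Besides the comparisons where the report says so, changes ran with length at a Spearman's rho over 0.3 in size: -0.315 for dehydration in WT, 0.439 for DSK2 RNAi in control, 0.419, 0.515, 0.42 and 0.467 for the dehydration interactions of atg7-2, DSK2 RNAi, bes1-D and bri1-301 and 0.353 for the starvation interaction of bri1-301. The further scaling removed over 0.1 of the median of all genes for starvation in WT (-0.19), atg7-2 (-0.48), DSK2 RNAi (-0.12), bes1-D (-0.28) and bri1-301 (-0.15). In control it did so for DSK2 RNAi (0.11), bes1-D (-0.18) and bri1-301 (0.17), and in interactions for dehydration in atg7-2 (0.12), DSK2 RNAi (0.20) and bes1-D (0.19) and starvation in atg7-2 (-0.26). Changes are to be read relative to these values.

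Control and dehydration libraries share replicate numbers. Deviations of libraries of the same number correlated at over 0.1 for every number in bes1-D (0.27, 0.16 and 0.26) and bri1-301 (0.34, 0.46 and 0.21), so the numbers were taken to pair the samples there, a pairing read from the data and not stated in the labels. In WT, atg7-2 and DSK2 RNAi they did not. Of the mutants' controls only those of DSK2 RNAi correlated with the WT controls of the same number at over 0.1 for every number (0.40, 0.24 and 0.29), so these were likewise taken as paired. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.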

Results

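RNA from leaves of Arabidopsis thaliana was sequenced in 40 libraries of WT, atg7-2, DSK2 RNAi, bes1-D and bri1-301 under 3 treatments. ATG7 is the activating enzyme that couples ATG8 to lipid in autophagy, DSK2 proteins are ubiquitin receptors, BES1 is a transcription factor of brassinosteroid signalling and BRI1 is the brassinosteroid receptor. Plants were 4 weeks old and were left as controls (3 libraries per genotype), dehydrated for 4 hours (3) or starved of fixed carbon for 5 days (2). The deposited values are reads scaled to library size (RPM, as the authors name the unit). A count of 3 reads is 0.101 to 0.114 RPM. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. Values are mean RPM ± SD with n = 3 for control and dehydration and n = 2 for starvation. Changes are differences of log2(RPM + 0.5), which understate the change of low genes, with limma's standard error (SE) and adjusted p. The first component of all libraries held 61.4% of the variance and the second 16.2%.

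The targeted transcripts were compared first. DSK2A in DSK2 RNAi was 6.63 ± 0.721 RPM in control, 8.03 ± 0.798 in dehydration and 9.85 ± 0.485 in starvation, against 69.0 ± 7.5, 71.7 ± 21.8 and 56.4 ± 4.56 in WT. DSK2B, its neighbour and close relative, was 14.8 ± 0.859 in control and 17.2 ± 1.14 in dehydration, against 133 ± 2.38 and 145 ± 21.6 in WT, but 155 ± 43.7 in starved DSK2 RNAi against 215 ± 7.08 in starved WT. How reads shared by both genes were counted is not given in the sources used here. BES1 was 424 ± 83.8 in bes1-D control leaves and 288 ± 33.8 in WT (log2 0.55, SE 0.18, adjusted p = 0.033), a call lost when only the compared libraries were fitted. In bes1-D it was 436 ± 104 in dehydration and 87.1 ± 9.23 in starvation, against 247 ± 12.3 and 65.3 ± 4.69 in WT. BRI1 was 176 ± 18.4 in bri1-301 and 106 ± 17.0 in WT (log2 0.74, adjusted p = 0.517), and 112 ± 17.3 and 66 ± 31.1 under dehydration and 46.1 ± 22.9 and 22.9 ± 2.47 under starvation. ATG7 was 16.5 ± 1.99 in atg7-2 and 11.3 ± 0.893 in WT (log2 0.52, adjusted p = 0.333), and 26.2 ± 7.61 and 15.8 ± 5.19 under dehydration and 77.8 ± 5.03 and 43 ± 13.7 under starvation. A count over a whole gene does not show an insertion or a point mutation, so the values of BES1, BRI1 and ATG7 do not check these labels.

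Control leaves of bes1-D, in which BES1 is dominantly active, carried less of the brassinosteroid biosynthetic transcripts and more of the growth transcripts than WT. BR6OX2, which makes the last step to brassinolide, was 0.429 ± 0.143 against 12.0 ± 0.897 RPM (log2 -3.76, SE 0.26, adjusted p = 4.8e-12). CPD, a cytochrome P450 of the pathway, was 51.8 ± 7.7 against 313 ± 13.9 (log2 -2.59, adjusted p = 1.24e-11). SAUR21, an auxin-induced growth gene, was 66.2 ± 22.2 against 18.5 ± 1.57 (log2 1.77, adjusted p = 1.83e-05). BRI1 fell from 106 ± 17.0 to 41.8 ± 14.3 (log2 -1.39, adjusted p = 0.00675). Of 10 brassinosteroid biosynthesis genes 6 fell over all genes tested and 7 adjusted over the list alone, none rose, and the list stayed called with either correlation (camera adjusted p = 1.9e-07; adjusted p = 0.00136 with an estimated correlation). Of 22 brassinosteroid- and auxin-induced growth genes 10 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 7.06e-08; adjusted p = 0.176 with an estimated correlation). XTH24, a wall-modifying enzyme, was the member that fell (log2 -1.74, adjusted p = 0.000741).

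Defence, metabolic and other transcripts also separated bes1-D from WT. In the salicylic acid and defence list 9 of 24 members rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 1.97e-05; adjusted p = 0.395 with an estimated correlation). NIMIN1, which binds the salicylic acid receptor NPR1, was 11.7 ± 6.00 against 0.745 ± 0.515 RPM (log2 3.25, adjusted p = 1.95e-06), and the glutaredoxin gene GRX480 26.5 ± 10.7 against 2.45 ± 0.234 (log2 3.13, adjusted p = 4.87e-08). PR2 and PR5, pathogenesis-related proteins named after their values were seen, fell (log2 -2.06 and -1.35). Glucosinolate biosynthesis fell in 12 of 17 members (14 adjusted over the list alone; camera adjusted p = 9.46e-07; adjusted p = 0.395 with an estimated correlation), with CYP79F1 at 17.9 ± 3.80 against 97.5 ± 29.9 RPM and its regulator MYB29 at 3.64 ± 1.75 against 16.5 ± 5.56. Sugar starvation genes fell in 6 of 14 members (8 adjusted over the list alone; camera adjusted p = 0.00592; adjusted p = 0.657 with an estimated correlation), DIN1, a dark-inducible gene, from 2800 ± 373 to 900 ± 356 RPM (log2 -1.70, adjusted p = 0.00024). Branched-chain amino acid genes fell in 5 of 9 members (7 adjusted over the list alone; camera adjusted p = 0.00134; adjusted p = 0.52 with an estimated correlation), among them BCAT2 (log2 -1.62) and IVD (log2 -1.18). Among WRKY transcription factor genes WRKY53 rose (131 ± 57.1 against 39.4 ± 14.5; log2 1.67, adjusted p = 0.00469) and so did WRKY46 (log2 1.27, adjusted p = 0.0178). The transcripts raised most, besides MRD1 and HEI10, were DDF1, a dehydration-responsive element binding factor (23.2 ± 15.3 against 0.195 ± 0.121; log2 4.92), and IGMT3, an indole glucosinolate methyltransferase (102 ± 33.5 against 3.22 ± 0.405; log2 4.75). Those lowered most besides BR6OX2 were ECS1 (182 ± 48.9 against 2960 ± 336; log2 -4.05), MIR167d (log2 -3.64) and PDS1, a dioxygenase of tocopherol synthesis (24.8 ± 4.39 against 259 ± 30.8; log2 -3.37). DDF1, IGMT3, ECS1, MIR167d, GRX480, CYP79F1 and BCAT2 lie within 1000 tested genes of BES1 in gene order. Floral transcripts fell in 4 of 9 members (camera adjusted p = 0.00709; adjusted p = 0.52 with an estimated correlation; 6 adjusted over the list alone), SEP2 among them at 0.171 ± 0.149 against 0.896 ± 0.0933 RPM.

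In bes1-D control leaves 3109 of 19824 genes passed, 1352 higher and 1757 lower, and the median of all genes was -0.20. A further scaling by median of ratios removed -0.18 of that median and left 1797 higher and 1307 lower, 57.9% higher against 43.5%. The count was 1098 with only the compared libraries (582 higher), 4469 and 1665 without bes1-D control replicate 2 (1302 higher) and 3 (1026 higher), 1983 without WT control replicate 3 (1061 higher) and 2024 without WT control replicate 1. The difference ran with transcript length (Spearman's rho -0.361 across genes), and with each library's length trend removed 3337 passed, 1326 higher and 2011 lower. Slopes of expression on log2 transcript length were -0.15, -0.165 and -0.43 in the bes1-D controls and -0.01 ± 0.139 in those of WT. Replicate 3 of bes1-D stood apart by this slope, and its 10 most abundant genes held 16.8% of its total.

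In bri1-301, a weak allele of the receptor, brassinosteroid biosynthetic transcripts were higher and growth transcripts lower than in WT. BR6OX2 was 138 ± 42.5 RPM against 12.0 ± 0.897 in WT (log2 3.42, SE 0.26, adjusted p = 2.19e-10) and ROT3, another P450 of the pathway, 18.1 ± 2.44 against 2.72 ± 0.76 (log2 2.55, adjusted p = 2.33e-10). PRE6, a growth-promoting helix-loop-helix factor, was 26.7 ± 7.92 against 156 ± 16.2 (log2 -2.57, adjusted p = 2.55e-07), and the expansin EXPA8 44.3 ± 8.81 against 199 ± 55.6 (log2 -2.14, adjusted p = 0.00966). Of the brassinosteroid biosynthesis genes 6 of 10 rose, 7 adjusted over the list alone (camera adjusted p = 2.13e-18; adjusted p = 1.16e-06 with an estimated correlation). Of the growth genes 15 of 22 fell, 18 adjusted over the list alone (camera adjusted p = 3.45e-51; adjusted p = 6.34e-06 with an estimated correlation). Photosynthesis genes had a median of -0.35 with 0 of 38 called over all genes or adjusted over the list alone, while the list as a whole fell (camera adjusted p = 4.65e-20; adjusted p = 0.0415 with an estimated correlation). Flavonoid genes had a median of -0.81, with 6 of 14 lower adjusted over the list alone (camera adjusted p = 4.68e-15; adjusted p = 0.0415 with an estimated correlation). The other genes lowered most were the extensin gene LRX2 (log2 -2.60), PYD4, a gene of pyrimidine breakdown (log2 -2.29), and the expansin EXPA11 (12.2 ± 3.30 against 58.8 ± 12.6; log2 -2.24). WRKY6 was 47.5 ± 13.3 against 24.8 ± 2.74 RPM (log2 0.89, adjusted p = 0.0402), a call that edgeR, DESeq2 and a further scaling did not keep.

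The bri1-301 controls differed from WT in 191 genes, 74 higher and 117 lower, and the median of all genes was 0.16. Median-of-ratios scaling removed 0.17 of that median and gave 54 higher and 168 lower, 24.3% higher against 38.7%. The difference ran with transcript length (Spearman's rho 0.419), with slopes of 0.158 ± 0.067 in bri1-301. With the length trend removed 126 were higher and 107 lower, and the photosynthesis list stayed called (camera adjusted p = 5.86e-15). The count was 38 with only the compared libraries, 372 with DESeq2 and 528 without the libraries that stand apart by length slope (340 higher). It was 84, 98 and 305 (166 higher) without bri1-301 control replicate 1, 2 and 3 and 105 without WT control replicate 1. The plot of control libraries shows the mutants' opposite positions for the genes named here.

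**Figure D1:**
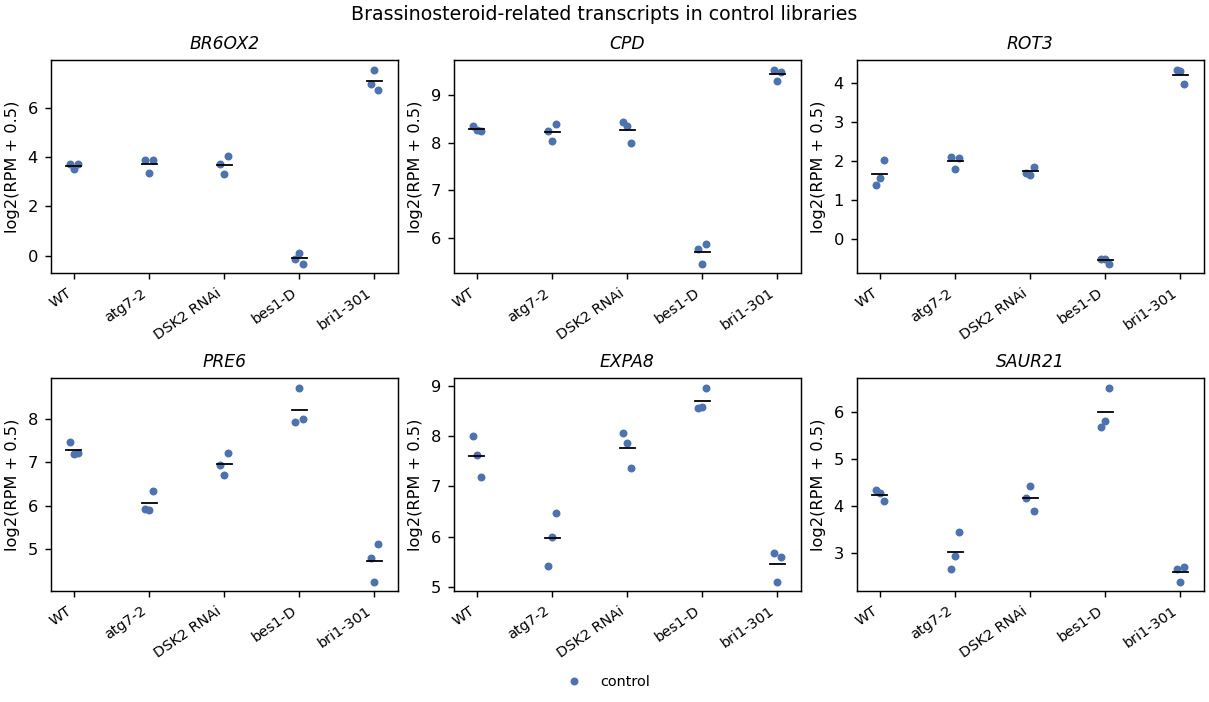
Each panel plots log2(RPM + 0.5) of a brassinosteroid-related transcript in the 3 control libraries of each genotype, a dot per library with a bar at the mean. BR6OX2 is at 0.429 RPM on average in bes1-D, 12.0 in WT and 138 in bri1-301, and PRE6 at 156 in WT and 26.7 in bri1-301.

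Control leaves of atg7-2 carried more senescence and defence transcripts and less growth transcripts than WT. SAG12, a senescence-associated cysteine protease and the annotated neighbour of ATG7, was 84.5 ± 104 against 2.06 ± 0.867 RPM (log2 4.35, SE 0.72, adjusted p = 0.000895), and 3.33 on the log2 scale without atg7-2 control replicate 3. NYE1, which starts chlorophyll breakdown, was 74.1 ± 7.55 against 32.5 ± 11.2 (log2 1.23, adjusted p = 0.00184). ALD1, an enzyme of pipecolic acid synthesis, was 18.0 ± 3.39 against 3.25 ± 2.46 (log2 2.5, adjusted p = 0.00516) and PBS3, an enzyme of salicylic acid synthesis, 24.0 ± 1.33 against 6.68 ± 1.86 (log2 1.81, adjusted p = 0.00759). Senescence genes rose in 7 of 16 members, 10 adjusted over the list alone (camera adjusted p = 2.22e-09; adjusted p = 0.0141 with an estimated correlation). Salicylic acid and defence genes rose in 8 of 24, 9 adjusted over the list alone (camera adjusted p = 2.22e-09; adjusted p = 0.091 with an estimated correlation). Growth genes fell in 12 of 22, 15 adjusted over the list alone (camera adjusted p = 1.85e-15; adjusted p = 0.0141 with an estimated correlation), EXPA8 to 65.0 ± 23.3 RPM (log2 -1.64) and XTH19, a wall enzyme, to 0.894 ± 0.136 from 3.52 ± 0.84 (log2 -1.51).

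Autophagy transcripts as a list were higher in atg7-2 control leaves, with a median of 0.45 and 1 of 33 members past the test (2 adjusted over the list alone; camera adjusted p = 7.1e-07; adjusted p = 0.0256 with an estimated correlation). That member was the cargo receptor NBR1, at 855 ± 77.5 against 583 ± 17.7 RPM (log2 0.55, adjusted p = 0.0405), a call lost with edgeR, DESeq2 and a further scaling. Among abscisic acid (ABA) and dehydration genes 3 of 36 rose, 8 adjusted over the list alone (camera adjusted p = 3.29e-07; adjusted p = 0.412 with an estimated correlation), including the dehydrin RAB18 (log2 1.33, adjusted p = 0.0299) and the phosphatase HAB1 (log2 0.96, adjusted p = 0.047). Sugar starvation genes rose in 2 of 14, 5 adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.421 with an estimated correlation), DIN2, a beta-glucosidase, reaching 29.5 ± 11.7 against 5.03 ± 2.92 RPM (log2 2.51, adjusted p = 0.04), and DIN9 (log2 0.89). Photosynthesis genes had a median of -0.27 with 1 of 38 lower, RBCS1A of the Rubisco small subunit (log2 -0.56, adjusted p = 0.0495), and none adjusted over the list alone (camera adjusted p = 1.84e-05; adjusted p = 0.421 with an estimated correlation). Epidermis markers had a median of -0.43 with 1 of 8 lower, PDF1 (log2 -0.85, adjusted p = 0.00868), and 2 adjusted over the list alone (camera adjusted p = 0.00465; adjusted p = 0.391 with an estimated correlation). Floral markers had a median of 0.40 with none of 9 called on either count (camera adjusted p = 0.0285; adjusted p = 0.525 with an estimated correlation). The polygalacturonase gene PGAZAT rose (13.7 ± 8.42 against 0.552 ± 0.174; log2 3.59), and XTH8 (log2 -2.14), EXPA16 (log2 -2.23), GASA6 (log2 -2.0) and ENODL8 (log2 -1.71) were lowered most. In all, 939 genes passed, 462 higher and 477 lower. The count was 436 with only the compared libraries (284 higher), 1657 with DESeq2 and 2057 without the libraries that stand apart by length slope (1105 higher). It was 355 and 396 (243 higher) without atg7-2 control replicate 3 and 2, and 415 (219 higher) and 475 without WT control replicate 1 and 2.

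DSK2 RNAi control leaves differed from WT in 13 genes, 8 higher and 5 lower. DSK2A (log2 -3.28, SE 0.20, adjusted p = 7.23e-13) and DSK2B (log2 -3.13, adjusted p = 1.11e-14) fell, as did AXS1, a synthase of apiose and xylose precursors (102 ± 2.06 against 285 ± 40.4; log2 -1.46), and the expansin EXPA16 (log2 -3.15, adjusted p = 0.00933). MAF5, a repressor of flowering, rose (14.5 ± 3.54 against 4.35 ± 1.46; log2 1.65). Flavonoid genes had a median of -0.82 with 0 of 14 called over all genes and 1 lower adjusted over the list alone (camera adjusted p = 1.39e-15; adjusted p = 0.112 with an estimated correlation). ABA and dehydration genes had a median of -0.31 with none called over all genes or adjusted over the list alone (camera adjusted p = 1.74e-08; adjusted p = 0.349 with an estimated correlation). The count was 30 with DESeq2 (13 higher, 17 lower), 25 without the libraries that stand apart, 23 without WT control replicate 2 (8 higher, 15 lower) and 29 without DSK2 RNAi control replicate 2.

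MRD1 and HEI10, neighbours in the annotation, were higher in each mutant than in WT. In control leaves MRD1 was 0.252 ± 0.143 RPM in WT and higher by 4.81, 4.82, 5.31 and 4.80 on the log2 scale in atg7-2, DSK2 RNAi, bes1-D and bri1-301. HEI10, a factor of meiotic crossover, was 1.09 ± 0.185 in WT and 25.0 ± 1.06, 23.3 ± 1.89, 30.5 ± 3.53 and 22.8 ± 1.45 in the same order. With AT3G05170, singled out after its values were seen, they were the 3 genes called in the same direction in all 4 mutants.

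Effects of the genotypes in control leaves were compared across 19824 genes, which are not independent replicates, and against unchanged groups simulated with shared controls (100 draws). For bes1-D and bri1-301 Pearson's r was -0.10 against 0.46 ± 0.28 (SD) simulated, and the covariance -0.021 against 0.037. Of genes called in both, 66 went in opposite directions, against 14.5 for independent lists, 21 were higher in both (5.05) and 8 lower in both (10.4). For bri1-301 and atg7-2 r was 0.37 against 0.43 ± 0.30, the covariance 0.054 against 0.034, and 49 genes were lower in both against 2.82 for independent lists. For bes1-D and atg7-2 r was 0.05, with a covariance of 0.012 against 0.045, 119 genes higher in both (31.5), 40 lower in both (42.3) and 133 opposite (73.5). For bes1-D and DSK2 RNAi r was -0.03, and for DSK2 RNAi and atg7-2 0.14, with covariances of -0.005 and 0.016 against 0.041 and 0.048. With 3 WT controls no split left 2 in each part, so part of an excess may come from the shared controls.

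Dehydration for 4 hours raised ABA transcripts in WT leaves. The dehydrin RAB18 (AT5G66400) went from 26.3 ± 16.5 to 78.8 ± 26.8 RPM (log2 1.71, SE 0.36, adjusted p = 0.0403), HAI1 (AT5G59220), an ABA-induced phosphatase, from 14.0 ± 6.52 to 68.2 ± 27.5 (log2 2.27, SE 0.46, adjusted p = 0.0277) and LEA4-5 (AT5G06760), a late embryogenesis protein, from 1.58 ± 0.749 to 11.2 ± 5.86 (log2 2.44, SE 0.54, adjusted p = 0.0453). The ABA receptor gene PYL4 fell from 97.4 ± 80.2 to 11.0 ± 1.91 RPM (log2 -2.74, adjusted p = 0.0274), the wall enzyme gene XTH22 from 131 ± 65.8 to 13.7 ± 2.39 (log2 -3.09, adjusted p = 0.0403) and the ethylene response factor ERF104 from 90.8 ± 7.68 to 17.8 ± 3.42 (log2 -2.33, adjusted p = 0.00347). Of 36 ABA and dehydration genes 3 rose over all genes and 24 adjusted over the list alone, none fell, and the list was called with either correlation (camera adjusted p = 2.73e-33; adjusted p = 0.0236 with an estimated correlation). Senescence genes had a median of 0.37, with 0 of 16 called over all genes and 4 higher adjusted over the list alone (camera adjusted p = 3.43e-07; adjusted p = 0.0281 with an estimated correlation). Growth genes fell in 1 of 22 members, 7 adjusted over the list alone (camera adjusted p = 4.07e-06; adjusted p = 0.221 with an estimated correlation). Jasmonate genes had a median of 0.41 with 0 of 23 called on either count (camera adjusted p = 2.35e-06; adjusted p = 0.221 with an estimated correlation). The photosynthesis list was not called (median 0.04, mean -0.05; camera direction up, adjusted p = 0.414). The other genes named by the rule were LBD1 and DIP2, which rose (log2 2.18 and 2.62), and PYL6 and ERF6, which fell (log2 -2.69 and -1.90).

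In WT dehydration 59 genes passed, 23 higher and 36 lower, and 2534 had an unadjusted p under 0.05. With only the 6 WT libraries compared none passed, edgeR called 42 and DESeq2 513. The count was 1 without WT control replicate 1 or WT dehydration replicate 2, 3 and 5 without WT dehydration replicate 1 and 3, 8 without WT control replicate 2 and 392 without WT control replicate 3. WT dehydration replicate 3 stood apart in its slope on transcript length (-0.595), and 14 genes passed without the libraries that stand apart.

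Several of these genes also passed in the mutants. In DSK2 RNAi HAI1 rose from 7.89 ± 1.77 to 39.1 ± 7.42 RPM (log2 2.24, adjusted p = 0.00462) and LEA4-5 by 2.28 on the log2 scale (adjusted p = 0.0129), while RAB18 went from 17.1 ± 3.61 to 37.5 ± 8.18 (log2 1.11, adjusted p = 0.0869). In bes1-D RAB18 (log2 1.60, adjusted p = 0.0226) and LEA4-5 (log2 2.23, adjusted p = 0.0315) rose, and in bri1-301 RAB18 (log2 1.82, adjusted p = 0.0141) and HAI1 (log2 1.89, adjusted p = 0.0412). ERF104 fell in DSK2 RNAi (log2 -2.06, adjusted p = 0.00122), and its change was -0.64 in bes1-D (adjusted p = 0.732) and -1.14 in bri1-301 (adjusted p = 0.117). In atg7-2 none of these passed: RAB18 was 61.0 ± 21.3 in control and 80.1 ± 36.9 in dehydration (log2 0.34, adjusted p = 1), and HAI1 33.6 ± 9.98 and 79.0 ± 52.7 (log2 0.90, adjusted p = 0.808).

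**Figure D2:**
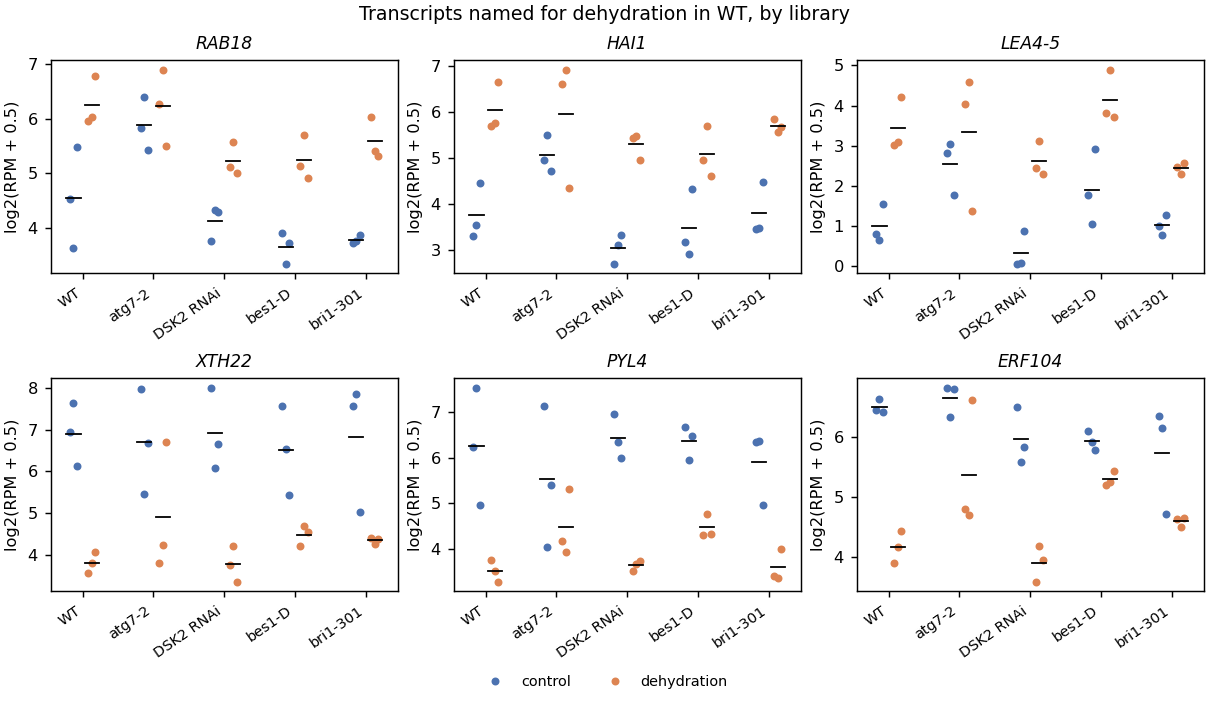
Each panel plots log2(RPM + 0.5) of a transcript named for dehydration in WT, a dot for each of the 3 control and 3 dehydration libraries of each genotype and a bar at the group mean. RAB18 rises from 26.3 to 78.8 RPM in WT and is at 61.0 and 80.1 in atg7-2, whose dehydration libraries spread more widely (SD 36.9).

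Among ABA and dehydration genes 15 of 36 rose in DSK2 RNAi (29 adjusted over the list alone; camera adjusted p = 6.68e-20; adjusted p = 0.139 with an estimated correlation), 9 in bes1-D (29 adjusted over the list alone; camera adjusted p = 4.73e-30; adjusted p = 0.0377 with an estimated correlation) and 12 in bri1-301 (24 adjusted over the list alone; camera adjusted p = 1.59e-34; adjusted p = 0.0198 with an estimated correlation). In atg7-2 none passed on either count, with a list median of 0.46 (camera adjusted p = 3.2e-09; adjusted p = 0.188 with an estimated correlation). Jasmonate genes rose in 5 of 23 in DSK2 RNAi (10 adjusted over the list alone; camera adjusted p = 6.5e-08; adjusted p = 0.139 with an estimated correlation) and 4 in bri1-301 (10 adjusted over the list alone; camera adjusted p = 2.77e-13; adjusted p = 0.0334 with an estimated correlation). Senescence genes rose in 6 of 16 in DSK2 RNAi (9 adjusted over the list alone; camera adjusted p = 7.38e-05; adjusted p = 0.139 with an estimated correlation), and in atg7-2 the list had a median of 0.50 with none called on either count (camera adjusted p = 8.12e-08; adjusted p = 0.049 with an estimated correlation). Growth genes fell in 4 of 22 in bri1-301 (9 adjusted over the list alone; camera adjusted p = 8.22e-10; adjusted p = 0.069 with an estimated correlation). Photosynthesis genes fell in 2 of 38 in DSK2 RNAi over all genes and adjusted over the list alone (camera adjusted p = 6.8e-07; adjusted p = 0.394 with an estimated correlation).

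Dehydration changed 758 genes in DSK2 RNAi (447 higher, 311 lower), 233 in bes1-D (79 and 154) and 158 in bri1-301 (86 and 72). Median-of-ratios scaling gave 330 higher and 460 lower in DSK2 RNAi (41.8% higher against 59.0%), 35 and 222 in bes1-D (13.6% against 33.9%) and 96 and 51 in bri1-301 (65.3% against 54.4%). In atg7-2 limma called 0 genes, with 1258 at an unadjusted p under 0.05, edgeR 0 and DESeq2 22, and limma 323 without atg7-2 dehydration replicate 3, 5 without atg7-2 control replicate 3 and 1 without atg7-2 control replicate 2. The DSK2 RNAi count was 224 and 360 (154 higher, 206 lower) without control replicate 1 and 2. It was 395, 308 and 322 without dehydration replicate 1, 2 and 3, 1302 with DESeq2 (546 higher, 756 lower) and 1697 without the libraries that stand apart. The bes1-D count was 20 without control replicate 1, 65 and 89 without dehydration replicate 1 and 2, 5 with only the compared libraries, 412 with DESeq2 and 494 without the libraries that stand apart. The bri1-301 count was 2, 8 (2 higher, 6 lower) and 549 (204 higher, 345 lower) without control replicate 1, 2 and 3. It was 5, 3 and 63 (27 higher, 36 lower) without dehydration replicate 1, 2 and 3. It was 412 with DESeq2 and 358 (178 higher, 180 lower) without the libraries that stand apart.

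Whether a response differed from that of WT was tested as an interaction. DDF1 fell under dehydration in bes1-D, from 23.2 ± 15.3 to 0.992 ± 0.0362 RPM, and was 0.195 ± 0.121 and 0.16 ± 0.0721 in WT (interaction log2 -3.73, SE 0.36, adjusted p = 4.93e-07). LOX4, a lipoxygenase of jasmonate synthesis, was 45.0 ± 20.0 in control and 8.54 ± 2.52 in dehydrated bes1-D, and 11.8 ± 1.68 and 18.0 ± 3.89 in WT (interaction log2 -2.87, adjusted p = 0.0231). The jasmonate list had an interaction median of -0.46 in bes1-D with 1 of 23 lower (5 adjusted over the list alone; camera adjusted p = 7.95e-10; adjusted p = 0.114 with an estimated correlation). In bes1-D 13 genes passed, all lower. Median-of-ratios scaling gave 3 higher and 26 lower (10.3% higher), edgeR 31, DESeq2 97 and the compared libraries alone none. The count was 3 without WT control replicate 1, WT dehydration replicate 3 or replicate 1 of bes1-D control or dehydration. It was 4, 5 and 8 without replicate 2 of WT control, WT dehydration and bes1-D dehydration. It was 20 without WT dehydration replicate 1 and 27 and 29 without bes1-D control replicate 2 and 3. For atg7-2, DSK2 RNAi and bri1-301 limma, edgeR and DESeq2 each called 0 genes (358, 532 and 199 at an unadjusted p under 0.05). No gene was shown to differ, nor a list with an estimated correlation. At the preset one camera called ABA (adjusted p = 4.14e-16) and photosynthesis genes (5.7e-17) lower in atg7-2 and the latter in DSK2 RNAi (3.27e-12). In bri1-301 flavonoid genes were among those higher (0.00128).

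Each response was also set against that of WT across genes, which are not independent replicates. For dehydration Pearson's r was 0.54 in atg7-2, 0.64 in DSK2 RNAi, 0.45 in bes1-D and 0.70 in bri1-301. The SD of the changes across genes, noise included, was 0.78, 1.13, 0.87 and 0.99 times that in WT, in the same order. Dehydration-responsive genes were then taken from these same libraries, leaving out WT and the mutant tested, so they are no independent evidence of direction. Genes that dehydration raised in at least 2 of the 3 other mutants had a median of 0.50 in atg7-2 control leaves against WT (73 genes, 8 higher and 1 lower; camera adjusted p = 1.23e-06; adjusted p = 0.384 with an estimated correlation). The medians of such raised genes were -0.65 in DSK2 RNAi (14 genes; adjusted p = 3.02e-08; adjusted p = 0.292 with an estimated correlation), -0.49 in bes1-D (46 genes; adjusted p = 0.0366; adjusted p = 0.647 with an estimated correlation) and -0.13 in bri1-301 (29 genes; adjusted p = 8.92e-06; adjusted p = 0.384 with an estimated correlation). Genes lowered in the other mutants had medians of -0.14 (adjusted p = 0.0343; adjusted p = 0.647 with an estimated correlation), 0.22 (adjusted p = 0.0216; adjusted p = 0.531 with an estimated correlation), 0.40 (adjusted p = 1.23e-06; adjusted p = 0.384 with an estimated correlation) and 0.19 (adjusted p = 0.65) in the same order of mutants.

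**Figure D3:**
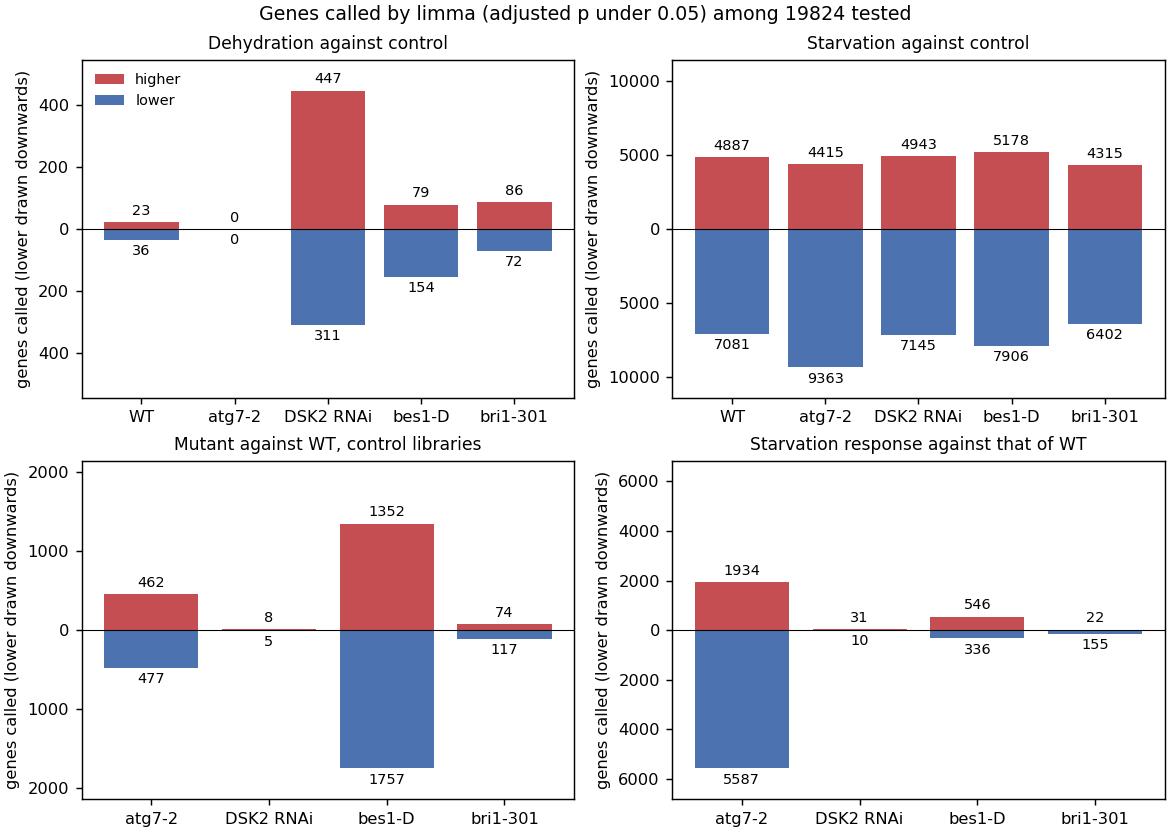
Bars count the genes called by limma among 19824 tested, higher upwards and lower downwards, for dehydration and starvation in each genotype, for mutants against WT in control and for starvation responses against that of WT. Dehydration gives 0 calls in atg7-2 and 758 in DSK2 RNAi, and starvation 4887 higher and 7081 lower in WT.

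Starvation for 5 days lowered photosynthetic transcripts and raised ABA, starvation and senescence transcripts in WT leaves. LHCB1.2, a chlorophyll-binding antenna protein, went from 3150 ± 454 to 1.36 ± 0.026 RPM (log2 -10.71, SE 0.31, adjusted p = 3.37e-22). The antenna gene LHCB3 went from 5870 ± 1070 to 39.4 ± 7.62 (log2 -7.20, adjusted p = 5.12e-23). RAB18 rose from 26.3 ± 16.5 to 2170 ± 227 (log2 6.53, adjusted p = 1.71e-14), the beta-glucosidase gene DIN2 from 5.03 ± 2.92 to 2070 ± 834 (log2 8.64, adjusted p = 1.54e-10) and SWEET15, a sugar transporter of senescing leaves, from 1.61 ± 0.702 to 344 ± 67.8 (log2 7.40, adjusted p = 6.79e-08). All 38 photosynthesis genes fell (median -4.31; camera adjusted p = 3.88e-28; adjusted p = 0.0414 with an estimated correlation). The LHCB1 genes are nearly identical and share reads in a way that the sources used here do not settle. Of the 21 lists only photosynthesis was called with an estimated correlation in WT starvation.

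Of 36 ABA and dehydration genes 26 rose and 5 fell (camera adjusted p = 6.43e-07; adjusted p = 0.262 with an estimated correlation). LEA4-5 (log2 6.78) and RD29B (log2 5.57) rose with RAB18, whereas COR15A and KIN1, cold-regulated genes named after their values were seen, fell (log2 -3.53 and -3.12). Sugar starvation genes rose in 10 of 14 (camera adjusted p = 6.45e-05; adjusted p = 0.257 with an estimated correlation), GDH2, a glutamate dehydrogenase, to 763 ± 13.5 from 104 ± 51.7 RPM and DIN9 to 59.4 ± 10.9 from 2.61 ± 0.0688. Branched-chain amino acid genes rose in 7 of 9 (camera adjusted p = 0.000712; adjusted p = 0.262 with an estimated correlation), PRODH1, the proline dehydrogenase, to 2220 ± 232 from 318 ± 292, BCAT2 (log2 2.65) and DIN4 (log2 2.48). Senescence genes rose in 11 of 16 and 1 fell (camera adjusted p = 0.000214; adjusted p = 0.179 with an estimated correlation), the nuclease BFN1 from 1.47 ± 0.981 to 52.8 ± 4.19 RPM and NYE2 from 25.3 ± 8.79 to 246 ± 44.3. Autophagy genes rose in 10 of 33 and 1 fell (camera adjusted p = 0.00825; adjusted p = 0.257 with an estimated correlation), ATG8H from 22.4 ± 7.5 to 164 ± 4.12 (log2 2.91), ATG8B (log2 2.27) and ATG7 itself (log2 1.85). Clock genes rose in 8 of 14 and 1 fell (camera adjusted p = 0.0125; adjusted p = 0.448 with an estimated correlation): the morning genes LHY (log2 4.14) and RVE8 (log2 2.84) rose and the evening gene GI fell (log2 -2.79). The hour of sampling is not given in the sources used here.

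Growth and division transcripts fell in starved WT leaves. Of 22 growth genes 18 fell and 2 rose (camera adjusted p = 6.43e-07; adjusted p = 0.179 with an estimated correlation), EXPA8 from 199 ± 55.6 to 2.22 ± 0.373 RPM (log2 -6.17), PRE6 (log2 -6.01) and SAUR20 (log2 -5.22). All 15 cell cycle genes fell (camera adjusted p = 2.1e-06; adjusted p = 0.204 with an estimated correlation), among them CDC20.1, an activator of mitotic proteolysis (log2 -3.24), PCNA1 (log2 -2.99) and MCM5 (log2 -2.93). All 17 glucosinolate genes fell (camera adjusted p = 1.26e-08; adjusted p = 0.179 with an estimated correlation), CYP83A1 from 275 ± 97.3 to 0.752 ± 0.301 RPM (log2 -7.73), CYP79F1 (log2 -7.35) and BCAT4 (log2 -7.18). Flavonoid genes fell in 13 of 14 (camera adjusted p = 0.000816; adjusted p = 0.396 with an estimated correlation), with CHS, chalcone synthase, at 0.887 ± 0.159 against 94.7 ± 44.3 RPM and GSTF12 lower by log2 -3.51. LDOX was listed at 0 in both starvation libraries and at 8.71 ± 8.52 RPM in control, at least 84.6-fold lower against 3 reads per library (0.103 RPM), a floor that covers counting error only. Without WT control replicate 3, at 18.6 RPM, the control mean was 3.79 RPM and the limit 36.8-fold. All 7 xylem markers fell (camera adjusted p = 0.000101; adjusted p = 0.179 with an estimated correlation), XCP2 from 22.2 ± 7.85 to 0.101 ± 0.0947 RPM, XCP1 (log2 -4.64) and LAC4 (log2 -3.50).

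The remaining lists were not called by camera in WT starvation. Jasmonate genes fell in 11 of 23 and rose in 5 (adjusted p = 0.367), VSP1, a storage protein, from 462 ± 276 to 0.495 ± 0.129 RPM (log2 -8.71), VSP2 (log2 -6.98) and LOX2 (log2 -5.58). Salicylic acid and defence genes fell in 8 of 24 and rose in 2 (adjusted p = 0.479), PR2 (log2 -6.06) and PR5 (log2 -4.18) falling and GRX480 rising (log2 4.33). Brassinosteroid biosynthesis rose in 4 of 10 and fell in 2 (adjusted p = 0.479), DWF4 (log2 1.85) and ROT3 (log2 1.42) against DWF1 (log2 -1.87). Heat shock genes rose in 2 of 12 and fell in 3 (adjusted p = 0.479; median -0.06, mean 0.20), HSP17.4 (log2 3.42) and HSFA2 (log2 2.83) against BIP2 (log2 -2.12). Proteasome genes rose in 2 of 16 and fell in 4 (adjusted p = 0.94; median -0.07, mean -0.18, camera direction up), RPT3 (log2 0.97) against RPN1A (log2 -1.29) and RPN2A (log2 -1.59). A further scaling turned the medians of the heat shock and proteasome lists positive. Of the markers of other cell types, guard cell genes fell in 5 of 9 (adjusted p = 0.194), the myrosinase gene TGG1 from 3430 ± 281 to 140 ± 19.2 RPM, MYB60 (log2 -1.62) and KAT1 (log2 -1.93). Phloem genes fell in 3 of 8 (adjusted p = 0.313), SEOA (log2 -2.30), SEOB (log2 -2.24) and SUC2 (log2 -1.55), and epidermis genes fell in 3 of 8 and rose in 1 (adjusted p = 0.432), PDF1 (log2 -2.41) and ATML1 (log2 -1.46) against CER5 (log2 1.42). Floral genes rose in 2 of 9 and fell in 1 (adjusted p = 0.339), PI from 1.18 ± 0.195 to 14.8 ± 2.17 RPM and FUL (log2 1.48). Adjusted over the list alone, the counts in WT starvation were the same for each list but the proteasome, where 1 gene rose.

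The genes changed most by starvation in WT, besides those named, were LEA7, a late embryogenesis gene (0.505 ± 0.666 to 498 ± 99.5 RPM; log2 9.13), the peroxiredoxin gene TPX2 (AT1G65970; log2 8.01), SOM, a zinc finger regulator of germination (log2 7.76), and LEA18 (log2 7.40). LHCB1.1 (log2 -9.21), XTH7 (189 ± 5.19 to 0.0846 ± 0.0709 RPM; log2 -8.35) and CYP81F4, an indole glucosinolate enzyme (log2 -7.79), fell furthest with LHCB1.2 and VSP1. In all 11968 genes passed, 60.4% of those tested, 4887 higher and 7081 lower, and 8534 changed at least 2-fold. The median of all genes was -0.26, of which median-of-ratios scaling removed -0.19. The labels name no separate controls for the 5 days, and the same 3 WT controls serve both stresses. Across genes the dehydration and starvation responses of WT correlated at r = 0.39 (0.44 ± 0.31 simulated for unchanged groups with shared controls), with a covariance of 0.23 against 0.046. Of the genes called in both, 21 rose and 29 fell in both against 5.67 and 12.9 for independent lists, and 2 went in opposite directions against 17.1.

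Photosynthetic transcripts fell under starvation in each mutant, and DIN2 and RAB18 rose. LHCB1.2 changed by -10.74, -11.11, -10.87 and -9.97 on the log2 scale in atg7-2, DSK2 RNAi, bes1-D and bri1-301, and all 38 photosynthesis genes fell in each (adjusted p = 0.0482, 0.0362, 0.0798 and 0.0301 with an estimated correlation; camera adjusted p = 6.48e-23, 5.12e-29, 4.75e-24 and 3.16e-30). DIN2 rose by 8.89, 9.36, 8.45 and 7.97 and RAB18 by 4.95, 6.16, 6.77 and 6.96. Autophagy genes rose in 22 of 33 in atg7-2 and 3 fell (camera adjusted p = 3.18e-06; adjusted p = 0.0482 with an estimated correlation), and rose in 13 in DSK2 RNAi (camera adjusted p = 0.00186; adjusted p = 0.17 with an estimated correlation) and 18 in bes1-D (camera adjusted p = 0.00189; adjusted p = 0.26 with an estimated correlation). ATG8H reached 927 ± 186 RPM in atg7-2 (log2 4.87), 297 ± 7.63 in bes1-D (log2 4.08), 115 ± 9.02 in DSK2 RNAi (log2 2.52) and 67.7 ± 46.4 in bri1-301 (log2 1.44). Adjusted over the list alone these autophagy and photosynthesis counts did not change. Salicylic acid and defence genes fell in 15 of 24 in bri1-301 and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 0.00133; adjusted p = 0.349 with an estimated correlation). Starvation changed 13778 genes in atg7-2, 12088 in DSK2 RNAi, 13084 in bes1-D and 10717 in bri1-301. In atg7-2 4415 were higher and 9363 lower with a median of -0.52 over all genes, and 6952 higher and 7263 lower after median-of-ratios scaling (48.9% higher against 32.0%), which removed -0.48 of that median.

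**Figure D4:**
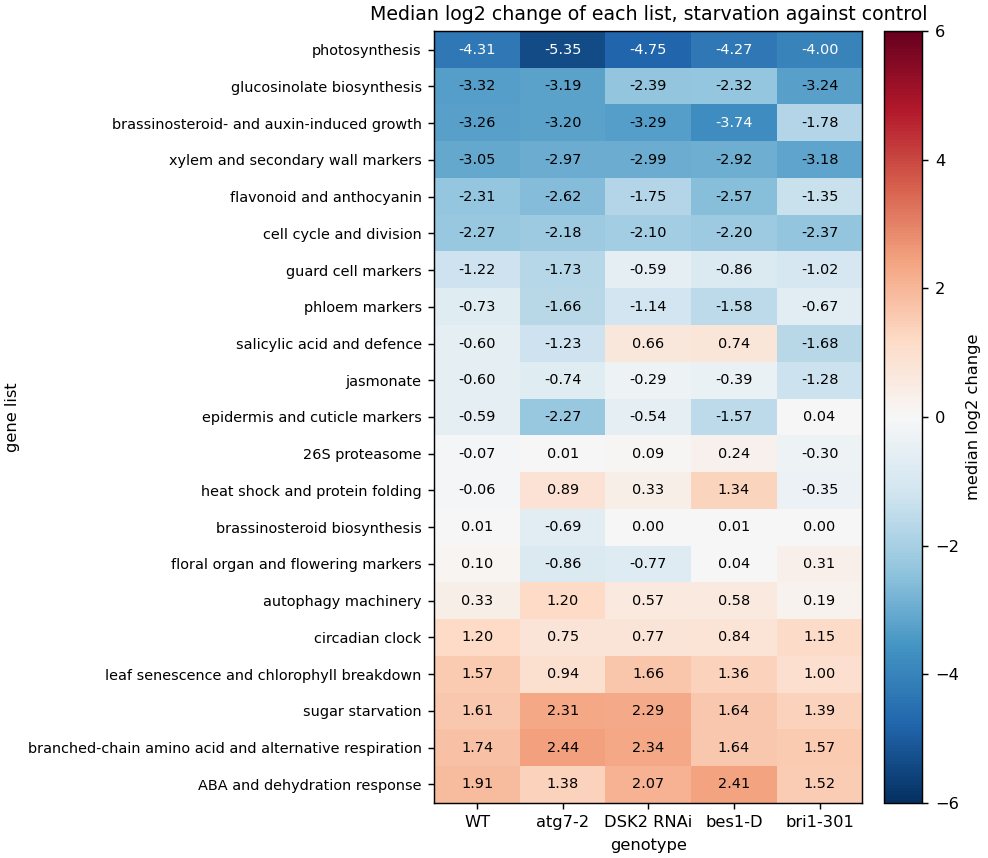
The heat map gives the median log2 change of each gene list under starvation against control, by genotype, red for higher and blue for lower. Photosynthesis is lowest in each column, from -5.35 in atg7-2 to -4.00 in bri1-301, and ABA and dehydration genes are highest in WT at 1.91.

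Starvation in atg7-2 differed from that in WT in 7521 genes, 1934 higher and 5587 lower. SUS5, a sucrose synthase of sieve elements, went from 1.13 ± 0.102 to 167 ± 9.20 RPM in atg7-2 and stayed at 0.815 ± 0.216 and 0.804 ± 0.374 in WT (interaction log2 6.72, SE 0.44, adjusted p = 8.19e-13). The arabinogalactan protein gene AGP14 went from 3.17 ± 0.895 to 109 ± 7.96 in atg7-2 and from 3.1 ± 0.811 to 0.665 ± 0.0349 in WT (log2 6.52, adjusted p = 1.12e-13). The lipid transfer protein genes LTP4 and LTP3 reached 160 ± 49.4 and 326 ± 55.8 in starved WT and 2.2 ± 0.609 and 12.3 ± 1.05 in starved atg7-2 (log2 -6.74 and -5.47, adjusted p = 0.000329 and 0.000397). In the autophagy list 15 of 33 members were higher and 3 lower in the interaction (16 and 4 adjusted over the list alone; camera adjusted p = 0.000314; adjusted p = 0.356 with an estimated correlation). ATG8H was higher (log2 1.96, adjusted p = 0.00331) and ATG8B lower (log2 -1.15, adjusted p = 0.0107), and among members named after their values were seen ATG11 (log2 3.96) and ATG9 (log2 2.84) were higher. Photosynthesis genes were lower in 26 of 38 (27 adjusted over the list alone; camera adjusted p = 0.000113; adjusted p = 0.893 with an estimated correlation). Sugar starvation genes were higher in 5 of 14 and lower in 2 on either count (camera adjusted p = 0.0317; adjusted p = 0.893 with an estimated correlation).

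**Figure D5:**
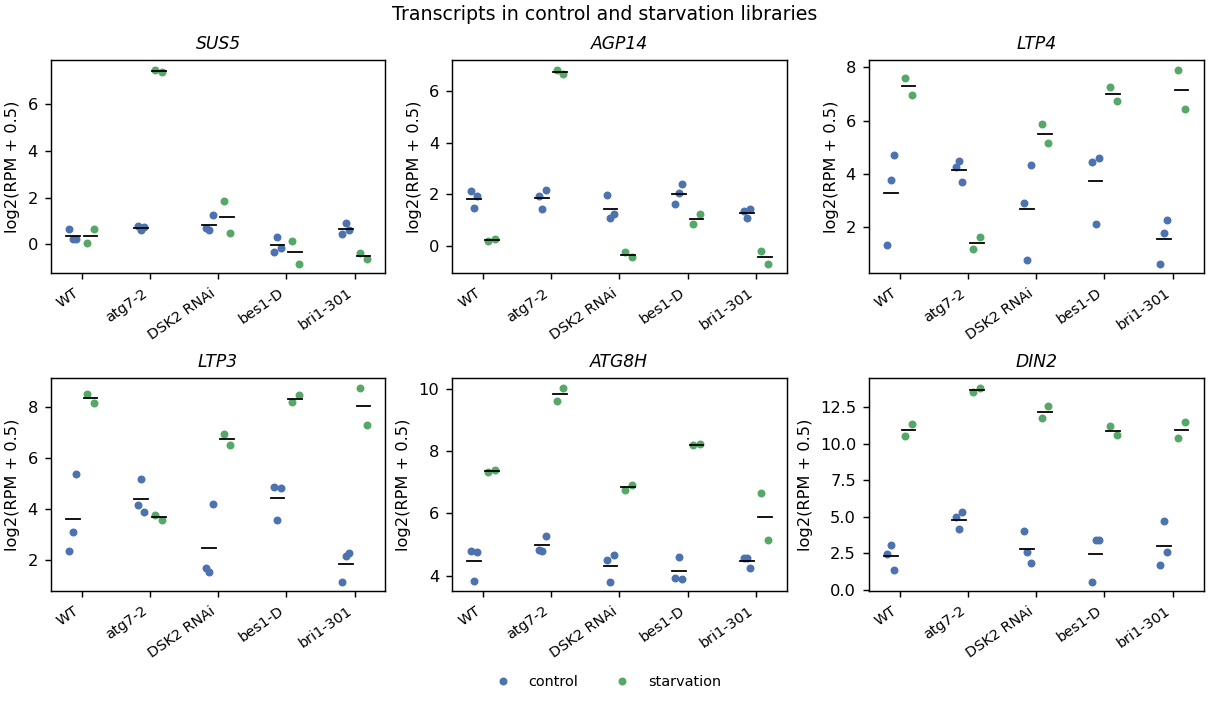
Each panel plots log2(RPM + 0.5) of a transcript in the 3 control and 2 starvation libraries of each genotype, a dot per library with a bar at the mean. SUS5 and AGP14 stand at 167 and 109 RPM in starved atg7-2, against 0.804 and 0.665 in starved WT.

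Libraries of starved atg7-2 had a slope of 0.441 ± 0.062 on log2 transcript length (n = 2) and those of starved WT -0.403 ± 0.132 (n = 2). The interaction ran with transcript length (Spearman's rho 0.502 across genes). After each library's length trend was removed, 6322 genes passed. In that fit the camera adjusted p at the preset correlation was 5.03e-05 for autophagy and 0.042 for photosynthesis genes. The sugar starvation list lost its call (camera adjusted p = 0.109). Median-of-ratios scaling gave 3929 higher and 3588 lower, 52.3% higher against 25.7%, and removed -0.26 of the median of all genes. Without WT starvation replicate 1 the count was 4957.

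In bes1-D 882 genes differed in their starvation response, 546 higher and 336 lower. DIN11, a dioxygenase of the starvation list, rose from 0.384 ± 0.171 to 85.3 ± 8.62 RPM in bes1-D and from 5.55 ± 2.16 to 29.2 ± 8.63 in WT (log2 4.28, SE 0.59, adjusted p = 9.05e-06). TPS04, a terpene synthase, was at 17.1 ± 6.52 in starved bes1-D and 1.71 ± 0.558 in starved WT (log2 4.14, adjusted p = 0.00147). DDF1 (log2 -4.50, adjusted p = 4.2e-09) and the defensin gene PDF1.2c (log2 -3.85, adjusted p = 0.035) had lower responses. Salicylic acid and defence genes were higher in 6 of 24 (7 adjusted over the list alone; camera adjusted p = 7.24e-06; adjusted p = 0.404 with an estimated correlation), and heat shock genes in 2 of 12 (3 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.404 with an estimated correlation). The count was 468 with only the compared libraries, 552 and 496 without WT starvation replicate 1 and 2, and 1544 (571 higher, 973 lower) and 535 without bes1-D starvation replicate 1 and 2, whose length slopes averaged -0.744 ± 0.308. Without bes1-D control replicate 3 there were 497 higher and 529 lower.

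In bri1-301 177 genes differed, 22 higher and 155 lower. PMZ, a stress-associated zinc finger gene, reached 21.3 ± 15.8 RPM in starved bri1-301 and 110 ± 25.2 in starved WT (log2 -3.74, adjusted p = 0.00715), and AIG1, a gene induced by bacterial effectors, went from 22.2 ± 11.8 to 1.00 ± 0.842 and from 9.39 ± 3.17 to 5.80 ± 0.652 (log2 -3.32, adjusted p = 0.0185). DREB1A (log2 2.94, adjusted p = 0.0136) and ARR7, a cytokinin response regulator (log2 2.48, adjusted p = 0.0423), had higher responses. Growth genes were higher in 3 of 22 (11 adjusted over the list alone; camera adjusted p = 2.49e-10; adjusted p = 0.146 with an estimated correlation) and salicylic acid and defence genes lower in 3 of 24 (8 adjusted over the list alone; camera adjusted p = 5.84e-10; adjusted p = 0.151 with an estimated correlation). The starvation libraries of bri1-301 had length slopes of 0.009 ± 0.646. Leaving out a starvation library, or the libraries that stand apart, left 1 starved library of a genotype, so such counts do not test robustness. The count was 108 without WT control replicate 3, and 96 and 103 without bri1-301 control replicate 1 and 2. No gene passed in limma with only the compared libraries (1214 at an unadjusted p under 0.05), and the count was 112 with edgeR.

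In DSK2 RNAi 41 genes differed in their starvation response, 31 higher and 10 lower. Compared directly in the same fit, starved DSK2 RNAi differed from starved WT in 3005 genes, 1899 higher and 1106 lower. DSK2B rose from 14.8 ± 0.859 to 155 ± 43.7 RPM, and from 133 ± 2.38 to 215 ± 7.08 in WT (log2 2.63, SE 0.25, adjusted p = 6.72e-08). GH3.3, which conjugates auxin to amino acids, went from 12.3 ± 2.54 to 82.6 ± 34.0 and from 14.1 ± 6.68 to 7.51 ± 1.62 in WT (log2 3.44, adjusted p = 0.0344). The sterol oxidase gene SMO1-2 had a lower response (log2 -1.07, adjusted p = 0.04). Photosynthesis genes had a median of -0.47 with none of 38 past the test over all genes and 13 lower adjusted over the list alone (camera adjusted p = 6.83e-07; adjusted p = 0.795 with an estimated correlation). This interaction ran with transcript length (Spearman's rho 0.589), with slopes of 0.282 ± 0.124 in starved DSK2 RNAi, and with the length trend removed the list gave a camera adjusted p of 0.0104. The count was 20 without WT control replicate 2, 21 without WT starvation replicate 2, 24 without DSK2 RNAi control replicate 1, 9 with only the compared libraries, 13 with edgeR, 61 with DESeq2 and 3268 without the libraries that stand apart. Across genes the starvation responses correlated with that of WT at r = 0.78 in atg7-2, 0.91 in DSK2 RNAi, 0.93 in bes1-D and 0.94 in bri1-301. The SD of the changes across genes, noise included, was 1.14, 1.03, 1.1 and 0.91 times that in WT, in the same order.

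The authors' deposited yes or no per gene rests on a threshold not given in the sources used here. By the authors' deposited table, yes is given to 554 genes for dehydration in WT, 55 of them among the 59 called here. For atg7-2, DSK2 RNAi, bes1-D and bri1-301 under dehydration the authors' deposited table gives yes to 111, 3573, 542 and 1640, with 730 of the 758, 197 of the 233 and 155 of the 158 calls here among the last 3. For control leaves the authors' deposited table gives yes to 2590, 95, 4513 and 604, which include 899 of the 939, 12 of the 13, 2603 of the 3109 and 182 of the 191 calls here. For starvation in WT, atg7-2, DSK2 RNAi, bes1-D and bri1-301 the authors' deposited table gives yes to 14529, 16655, 14765, 14313 and 9834. These include 94.9, 90.3, 96.1, 88.9 and 82.4% of the 11968, 13778, 12088, 13084 and 10717 genes called here. In bri1-301 the authors' deposited table gives fewer than were called here.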

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

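The tests of a transcript-length trend and of other splits, and the use of counts with 1 library left out to test for a single library, were chosen only after the result was seen.

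The interaction tests singled out responses that differ from that of WT: 13 genes for dehydration in bes1-D and, for starvation, 7521 in atg7-2, 882 in bes1-D, 177 in bri1-301 and 41 in DSK2 RNAi. Under dehydration in bes1-D DDF1 (log2 -3.73) and LOX4 (log2 -2.87) had lower responses. Under starvation in bes1-D DDF1 (log2 -4.50) and PDF1.2c (log2 -3.85) had lower and TPS04 (log2 4.14) and DIN11 (log2 4.28) higher responses. In bri1-301 AIG1 (log2 -3.32) and PMZ (log2 -3.74) had lower and ARR7 (log2 2.48) and DREB1A (log2 2.94) higher starvation responses. In DSK2 RNAi the starvation response of SMO1-2 (log2 -1.07) was lower and those of DSK2B (log2 2.63) and GH3.3 (log2 3.44) were higher. In atg7-2 LTP4 (log2 -6.74) and LTP3 (log2 -5.47) had lower and SUS5 (log2 6.72) and AGP14 (log2 6.52) higher starvation responses.

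The 7521 genes that responded to starvation differently in atg7-2 than in WT were followed up. A transcript-length trend between libraries is not the whole of it, since 6322 genes passed once the trend was removed, and the values before and after correlated at 0.84 across genes. It does shape the pattern: the median change ran from -0.94 in the shortest to 0.78 in the longest group of transcripts, and from -0.31 to -0.17 after removal. No single library accounts for it, since the lowest count with any 1 library left out was 4957, without WT starvation replicate 1. A starvation state further along in atg7-2 may contribute and stays open, because the interaction correlated at 0.14 with the starvation response of DSK2 RNAi, at -0.08 with that of bes1-D and at -0.07 with that of bri1-301.

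Splits of the control and dehydration libraries were counted for each comparison of 3 against 3, where 10 splits cannot give a share under 0.05. The real count against the highest other was 59 and 2 for dehydration in WT, 758 and 7 in DSK2 RNAi, 233 and 10 in bes1-D and 158 and 0 in bri1-301, each reached by 1 split, the real one. In atg7-2 the real count was 0 (1258 genes at an unadjusted p under 0.05, edgeR 0 and DESeq2 22), all 10 splits reached it and the highest other was 99. In control it was 939 and 50 for atg7-2, 13 and 5 for DSK2 RNAi, 3109 and 805 for bes1-D and 191 and 18 for bri1-301, again reached by 1 split each. Where libraries were taken as paired, 4 splits part all 3 pairs. Among these the highest other was 10 for dehydration in bes1-D, 0 in bri1-301 and 0 for DSK2 RNAi in control, against 1, 0 and 5 in the 6 others. Free splits of a dehydration interaction can exchange genotypes that differ and do not measure chance, so whole pairs of 1 number were exchanged between genotypes, in the fit with a replicate block within each genotype and without the starvation libraries. These are again 10 splits, too few for a share under 0.05. In bes1-D the real count in that fit was 10, 2 splits reached it and the highest other was 1264. For atg7-2, DSK2 RNAi and bri1-301 the real count of limma was 0, so all 10 splits reached it (872, 1393 and 356 genes at an unadjusted p under 0.05 in that fit, edgeR and DESeq2 0), with highest others of 1, 0 and 0. Splits of several times the real count, as in bes1-D here and within atg7-2, point to a structure of the samples, whose source was not tested.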

How the results depend on the processing

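The tests with a length correction, with the length slope as a covariate, without the libraries that stand apart and with a replicate block of the WT and DSK2 RNAi controls were chosen only after the result was seen. Outside single libraries left out, named genes kept direction and side of the threshold in 2262 of 2387 values (92 lost and 33 gained a call), gene lists in 5024 of 5417 (251 lost, 140 gained, 2 reversed) and counts stayed within 1.5 times in 225 of 281. With 1 library left out, named genes did so in 1010 of 1173 values (162 lost, 1 gained) and lists in 3195 of 3507 (123 lost, 183 gained, 6 reversed). An estimated correlation ended 171 of 462 list results. The cause was not tested, except that fewer libraries leave fewer degrees of freedom. Depth limits only genes near 0.101 to 0.114 RPM.

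Counts of calls moved as follows, in the order dehydration, control, dehydration interaction and starvation interaction. DESeq2 gave 513 in WT, 22 in atg7-2, 1302 in DSK2 RNAi, 412 in bes1-D and 412 in bri1-301 for dehydration. It gave 1657 in atg7-2, 30 in DSK2 RNAi and 372 in bri1-301 in control, and 97 for the bes1-D dehydration interaction. edgeR gave 31 for the last, and for starvation interactions 13 in DSK2 RNAi and 112 in bri1-301. The length slope as a covariate gave 318 in WT, 1720 in DSK2 RNAi, 498 in bes1-D and 524 in bri1-301 for dehydration. It gave 2609 in atg7-2 and 335 in bri1-301 in control, 48 for the bes1-D dehydration interaction, and 1944 in bes1-D and 355 in bri1-301 for starvation interactions. Removing the length trend gave 170 in WT and 246 in bri1-301 for dehydration. Median-of-ratios scaling gave 29 for the bes1-D dehydration interaction. No filter gave 28 for dehydration in WT, 105 for the DSK2 RNAi starvation interaction and a correlation of 0.61 between the dehydration responses of DSK2 RNAi and WT. The filter at 5 RPM gave 22 for that interaction and a correlation of 0.66. A pseudocount of 0.1 gave 13 and of 1 gave 68 for it, and a pseudocount of 1 gave 96 for dehydration in WT. Only the compared libraries gave limma 0 (WT; 2044 at an unadjusted p under 0.05, edgeR 42 and DESeq2 513 with all libraries), 1216 (DSK2 RNAi) and 5 (bes1-D) for dehydration, 436 (atg7-2), 1098 (bes1-D) and 38 (bri1-301) in control, 0 for the bes1-D dehydration interaction (612 unadjusted), and 9 (DSK2 RNAi), 468 (bes1-D) and 0 (bri1-301; 1214 unadjusted, DESeq2 226 with all libraries) for starvation interactions. Without the libraries that stand apart dehydration gave 14 in WT, 3 in atg7-2, 1697 in DSK2 RNAi, 494 in bes1-D and 358 in bri1-301. Control gave 2057 in atg7-2, 25 in DSK2 RNAi and 528 in bri1-301, the bes1-D dehydration interaction 32, and starvation interactions 3268 in DSK2 RNAi and 5549 in bri1-301. For dehydration in WT a replicate block shared by all groups gave 96, and a replicate block within each genotype together with leaving out the starvation libraries gave 217 (111 higher, 106 lower). Which of these 2 choices moved the latter was not tested. In bes1-D and bri1-301 the replicate block within each genotype, without the starvation libraries, kept counts within 1.5 times. It changed no list call for dehydration, nor those of DDF1 and LOX4 in the bes1-D interaction. In their interactions with WT this pair of choices ended the call of cell cycle genes in bes1-D (adjusted p 0.0212 to 0.0774) and gave calls in bri1-301 of growth (0.14 to 0.0447), branched-chain amino acid (0.0669 to 0.045), senescence (0.0669 to 0.0447) and salicylic acid genes (0.0669 to 0.0409). No other call there changed. WT control and dehydration libraries of the same number correlated at -0.37, 0.5 and 0.35. In DSK2 RNAi a replicate block with the WT controls gave 19 genes in control, 0 for the dehydration and 35 for the starvation interaction. It changed no call of a named gene or list. With the length trend removed in the same fit, 22 passed in control, and in the fit with the replicate block within each genotype 402 in bes1-D and 360 in bri1-301 for dehydration.

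With 1 library left out counts for dehydration ranged from 1 to 392 in WT, 0 to 323 in atg7-2, 224 to 769 in DSK2 RNAi, 20 to 256 in bes1-D and 2 to 549 in bri1-301. For starvation they ranged from 9789 to 11459, 11876 to 13268, 10148 to 11404, 10968 to 13181 and 9943 to 11249 in the same order. Starvation ranges include fits with 1 starved library left in a genotype. In control the ranges were 355 to 707 in atg7-2, 11 to 29 in DSK2 RNAi, 1665 to 4469 in bes1-D and 84 to 305 in bri1-301. For dehydration interactions they were 0 to 1, 0 to 0, 3 to 29 and 0 to 0, and for starvation interactions 4957 to 7398, 20 to 43, 496 to 1544 and 57 to 1651.

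Reversed list results are given as adjusted p, with the range over single libraries left out. Without WT control replicate 3 flavonoid genes reversed in atg7-2 control (0.0368; 0.0368 to 0.79), ABA genes in bri1-301 control (0.658; 8.22e-05 to 0.658), flavonoid genes in the bes1-D (0.0365; 0.0218 to 0.994) and bri1-301 (0.979; 1.65e-11 to 0.979) dehydration interactions and ABA genes in the latter (0.0193; 0.0193 to 0.934). Without bes1-D control replicate 3 photosynthesis genes reversed for dehydration in bes1-D (0.016; 8.55e-05 to 0.891). Without the libraries that stand apart ABA (0.0191) and photosynthesis genes (0.016) reversed in the bes1-D dehydration interaction. Medians of dehydration-responsive genes lost their call under scaling for lowered genes in atg7-2 (-0.09) and raised genes in DSK2 RNAi (-0.55) and bri1-301 (-0.13), with no filter for lowered genes in atg7-2 (-0.15) and DSK2 RNAi (0.15), and with a pseudocount of 0.1 for lowered genes in atg7-2 (-0.11) and DSK2 RNAi (0.22) and raised genes in bes1-D (-0.31).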

Other observations

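The tests of chance values of the shared WT controls, of a difference of the WT line and of crowding around BES1, and the interval given with the ratio of 0.45, were chosen only after the result was seen. All genes named here were chosen after their values were seen.

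ICS1 and PBS3, genes of salicylic acid synthesis, differed from WT in their starvation response in some mutants. ICS1, the isochorismate synthase, was 11.6 ± 2.1 RPM in starved WT (n = 2), 139 ± 19.1 in bes1-D, 93.5 ± 19.8 in DSK2 RNAi, 42.7 ± 1.37 in atg7-2 and 1.68 ± 0.52 in bri1-301. PBS3 was 11.1 ± 0.83 in WT, 89.2 ± 45.6 in bes1-D, 112 ± 52.6 in DSK2 RNAi, 58.2 ± 6.71 in atg7-2 and 1.86 ± 0.433 in bri1-301. The starvation response of ICS1 was higher than that of WT in bes1-D (log2 2.42, limma adjusted p = 0.000549) and DSK2 RNAi (log2 2.49, adjusted p = 0.00387), lower in bri1-301 (log2 -2.85, adjusted p = 0.000636) and not called in atg7-2 (log2 0.37, adjusted p = 0.541). That of PBS3 was higher in bes1-D (log2 2.93, adjusted p = 0.00354), lower in bri1-301 (log2 -2.91, adjusted p = 0.0159) and not called in DSK2 RNAi (log2 2.76, adjusted p = 0.0548) or atg7-2 (log2 0.52, adjusted p = 0.541). The salicylic acid and defence list of 24 genes was called by camera for this interaction in DSK2 RNAi (2 higher, 4 adjusted over the list alone; adjusted p = 0.000741; adjusted p = 0.795 with an estimated correlation) and not in atg7-2 (8 lower, 6 adjusted over the list alone; adjusted p = 0.639). No genotype's call held with an estimated correlation.

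MRD1, HEI10 and AT3G05170 were higher in every mutant than in WT. AT3G05170 lay between 0 and 0.0689 RPM in WT and between 1.74 and 22.3 in the mutants. Chance values of the shared WT controls are excluded, since all 24 differences of the 3 genes in dehydration and starvation passed too. Reads identical to another place in the reference cannot account for it, since at most 1% of their 50-base words occur elsewhere exactly. A copy with scattered mismatches, or one missing from the reference, was not tested. In 8 of 8 WT libraries all 3 genes lay below every mutant library, which restates how they were chosen. A difference of the WT line from the mutant lines stays open, since these values go with it but do not test it against other sources.

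Whether differences of bes1-D from WT crowd around BES1 in gene order was tested and did not pass. Of 720 genes called the same way in all 3 treatments 118 lay within 1000 tested genes of BES1 against 72.9 by their share, a ratio of 1.62 (p = 0.056 in a permutation test over 10000 rotations of the gene order). Among them AT1G23960 was lower by log2 -6.97 and AT1G19550 higher by log2 8.31 in control. Genes called in opposite directions in bes1-D and bri1-301 gave a ratio of 0.45 (3 of 66; 95% Clopper-Pearson interval 0.09 to 1.25 for independent genes). From 3 genes in control it cannot decide. Brassinosteroid signalling and a segment linked to BES1 that differs from WT stay open.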
